A study of Homo sapiens with 6 samples.

How the data were processed

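The study compared MCF-7 cells stably transfected with an shRNA against LINC00052 with MCF-7 cells carrying an shRNA against luciferase, 3 samples each. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin by the standard Affymetrix procedure. The values used are the authors' deposited probe set values, 1 table with a column per sample, and 0 of its columns were left out. They were read as log2 values: they have 2 decimals, run from 1.11 to 13.91, and have near-equal medians and quartiles in each deposited column. Neither the base of the logarithm nor the method of summarization and normalization is given in the sources used here, so each fold rests on the base being 2. Per the submitters' processing notes, Transcriptome Analysis Console and limma were used, with no version given. The genome build is not given in the sources used here.

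Probe sets were named from the platform annotation paired with the table: 16098 probe sets had 1 symbol, 0 had several and 32128 had none, and these last are unnamed here. All 16098 Entrez identifiers were found in the GRCh38.p14 gene table, which changed 0 symbols. That table was used only for names, for which genes code for protein and for which genes neighbour or overlap each other. For a gene with several probe sets (779 genes), the one with the highest mean over the 6 arrays stood for it in the gene lists. For 2 of these genes, MEX3A and TOMM40, probe sets were called in opposite directions.

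Groups were compared probe set by probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, two-sided) on the deposited values, over all 48226 probe sets and with Benjamini-Hochberg adjustment. The fit had the group as its only term. A probe set counted as changed at an adjusted p under 0.05, and a further count asked for a fold of at least 2. LINC00052 also had an exact permutation test of its 6 values. Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists with at least 8 measured genes. Members were also counted with the adjustment made over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

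The groups, the tests, the 34 gene lists, the rule for named genes and the alternatives, except as said below, were fixed before the data were examined. The rule named LINC00052 and NTRK3, the 12 probe sets with 1 symbol and the largest log2 fold change in each direction among those called and separating the groups, up to 4 members with the smallest adjusted p of each list that passed or had at least 3 called members, and ERBB3, ESR1, CDH1 and MKI67 whatever their values. Genes outside it are said to have been named after their values were seen.

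The alternatives were quantile normalization, centring each array on its median, leaving out dim probe sets, an intensity trend or robust variances in eBayes, array weights, the replicate number as a block, probe sets with a symbol only, a test against a fold of 1.2 (treat), leaving out each array, and for the lists an estimated correlation, fry, ranks and the mean of a gene's probe sets. Cyclic loess normalization, and protein-coding members only for the gene families, were added after seeing the data.

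Arrays were simulated for the 48226 probe sets with the control means and independent noise, with the variances shrunken by eBayes. The fit was tested on them for the comparison of the knockdown with the control. It recovered 7.46% of 67 probe sets changed by 0.5 on the log2 scale, 83.6% of 67 changed by 1 and 100% of 66 changed by 2, and 2.31% of its calls were false. In this simulation, with few probe sets changed, changes of 0.5 were mostly missed. The Benjamini-Hochberg threshold loosens as more probe sets change. These shares therefore do not carry over to the real arrays, where 6562 probe sets were called. On simulated arrays camera called the shifted list (adjusted p = 5.5e-70) and 1 of the other lists with the preset correlation, and the shifted list alone with an estimated correlation (adjusted p = 0.00118).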

Results

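RNA was measured on Affymetrix expression arrays in MCF-7, a human breast cancer cell line of luminal type that carries the oestrogen receptor. 3 arrays held RNA of cells stably transfected with a short hairpin RNA (shRNA) against LINC00052, a long non-coding RNA, and 3 held RNA of control cells with a hairpin against luciferase, which human cells do not make. Both lines had been selected in puromycin at 0.6 ug/ml for 14 days. The table held 48226 probe sets, of which 16098 carried 1 gene symbol each and named 14884 genes. The other 32128 probe sets are unnamed here. Array medians lay between 4.51 and 4.61 on the log2 scale. Across probe sets, which are not independent replicates, Pearson's r was 0.979 to 0.9827 between control arrays, 0.9889 to 0.9907 between knockdown arrays and 0.9645 to 0.9737 between the groups. The number of arrays limits the precision, and the labels do not say that the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

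LINC00052 itself, the target of the hairpin, fell in the knockdown cells, which checks the labels. Its signal was 8.54 ± 0.18 (SD, n = 3) in the control arrays and 6.80 ± 0.04 (SD, n = 3) in the knockdown arrays, a log2 fold change of -1.74 (SE 0.12) or a 3.33-fold lower level, with 30% of the control signal remaining. limma gave an adjusted p of 0.000369. The exact two-sided permutation test gave p = 0.1, the smallest p that 3 arrays against 3 allow. NTRK3, its neighbour, has no named probe set in the table used here, so its level was not analysed here.

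The comparison asked which transcripts differ between the cells with the LINC00052 hairpin and the control cells. The design does not separate the lowering of LINC00052 from other effects of the hairpin or from differences between the stable lines. Genes of DNA replication and cell division rose together, and part of the measured genes of sterol and fatty acid synthesis rose with them. Most of the measured genes of a hypoxia list fell. So did the transcripts of the secreted or surface proteins IGFBP5, ceruloplasmin (CP), CEACAM5 and fibronectin (FN1). Their log2 fold changes ran from -3.66 for IGFBP5 to -2.64 for FN1. With limma at an adjusted p under 0.05, 6562 of 48226 probe sets changed, 3836 higher and 2726 lower in the knockdown cells, and 1379 of them changed by at least 2-fold, 852 higher and 527 lower. The split moved with centring: with each array centred on its own median, 4569 probe sets were higher and 2083 lower, or 68.7% higher in place of 58.5%. Counting each gene once by its brightest probe set, 2136 genes were higher and 917 lower. The 2 groups did not overlap at 31.7% of probe sets, where chance gives 10%. Leaving out knockdown array 1, 2 or 3 lowered the count of changed probe sets to 3782, 3574 or 4094, and a test against a fold of 1.2 lowered it to 2559.

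FOLH1, which encodes prostate-specific membrane antigen, had the largest positive change among the named probe sets that passed, rising from 3.00 ± 0.06 to 7.09 ± 0.04 (SD, n = 3 each). Its log2 fold change was 4.09 (SE 0.10, limma adjusted p = 1.02e-05). The control level lay at the 18.3rd percentile of the array, near its floor, so the 17.1-fold size depends on background signal. Of the other 11 largest increases, CDC6, GINS2, MCM6 and MCM10 belong to the DNA replication and S phase list. CDC6, which helps load the replicative helicase, rose by 2.70 (SE 0.21) on the log2 scale, and GINS2 (2.57, SE 0.25), DTL (2.33, SE 0.20) and CDC7 (2.13, SE 0.17) also rose. The minichromosome maintenance genes MCM8 (2.20), MCM6 (2.17) and MCM10 (2.10), the exonuclease gene EXO1 (2.09) and the Myc target CDCA7 (2.22) followed. The imprinted, retrotransposon-derived gene PEG10 (2.48, SE 0.14) and the nucleolar gene LYAR (2.16, SE 0.16) completed the 12 largest increases.

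Among the decreases, the log2 fold change was -3.69 (SE 0.26) for S100A7 (psoriasin), -3.66 (SE 0.11) for IGFBP5, a binding protein of insulin-like growth factors, and -3.64 (SE 0.11) for CP, the copper-carrying ferroxidase. The knockdown level of S100A7 lay at the 28.3rd percentile of the array and that of MMP13 at the 33.4th, so the size of these 2 changes depends on background signal. For IGFBP5 the signal was 10.22 ± 0.08 in control and 6.56 ± 0.13 in knockdown arrays (SD, n = 3 each, limma adjusted p = 2e-05). The carcinoembryonic antigen gene CEACAM5 (-3.38, SE 0.12), complement factor B (CFB, -3.07, SE 0.10), the collagenase gene MMP13 (-2.79, SE 0.23) and CD68 (-2.73, SE 0.13) fell as well. FN1 (-2.64, SE 0.14), FOS (-2.63, SE 0.15), the immune checkpoint ligand gene VTCN1 (-2.58, SE 0.17) and SOX9 (-2.52, SE 0.10) followed. The probe set named MIR23C fell by 3.30 (SE 0.16). That microRNA gene lies within MAP7D2, whose own probe set, looked up after its host was seen, fell by 2.21 (SE 0.13), and the arrays do not show a mature microRNA level. FOLH1, CEACAM5 and S100A7 have close paralogs, and the sources used here do not say which copies their probe sets detect.

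**Figure D1:**
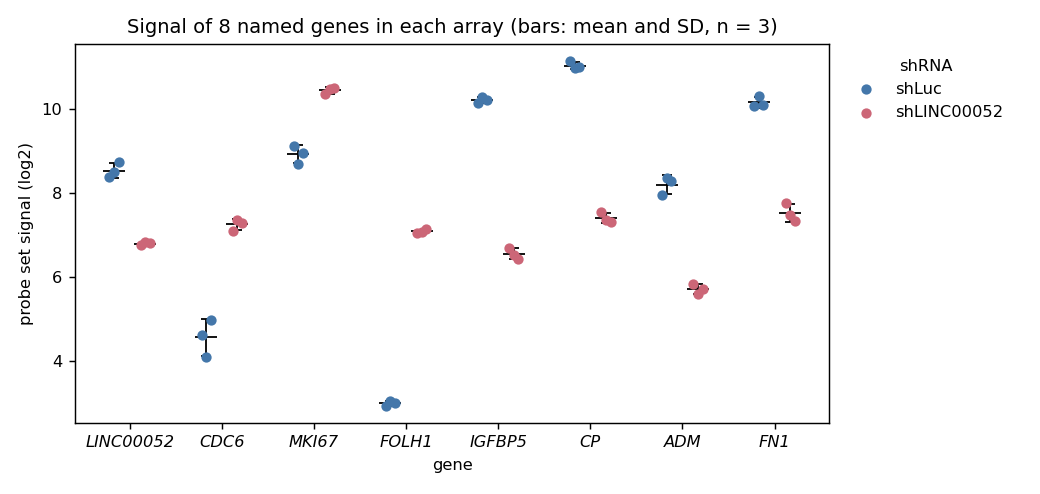
Signal (log2) of 8 named genes in each of the 6 arrays, control in blue and knockdown in red, with bars for the mean and SD (n = 3). The arrays of the groups do not overlap for any of these genes, and LINC00052 goes from 8.54 to 6.80 and FOLH1 from 3.00 to 7.09.

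Cell division genes moved as a block. All 25 measured members of the mitosis and G2/M list rose, with a median rise of 2.29-fold, and so did all 22 of the DNA replication and S phase list, with a median log2 fold change of 1.67. FOXM1, a transcription factor of mitotic genes, rose by 2.02 (SE 0.14) on the log2 scale, with CDC20 at 1.73 (SE 0.13), BIRC5 (survivin) at 1.62 (SE 0.11) and the mitotic kinase gene PLK1 at 1.45 (SE 0.11). MKI67, the proliferation marker Ki-67, rose by 1.52 (SE 0.13, limma adjusted p = 0.000626), MCM5 by 1.87 (SE 0.13) and RRM2, a subunit of ribonucleotide reductase, 3.47-fold. The camera test of limma gave adjusted p = 2.11e-18 for the mitosis list and 7.58e-17 for the replication list, and both had adjusted p = 0.162 with an estimated correlation. The counts adjusted over the list alone were also 25 and 22. None of the replication-dependent histone genes was measured under its current symbol.

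Lipid synthesis genes rose in part. Of 16 measured cholesterol synthesis genes, 9 rose (15 adjusted over the list alone) and 7 did not pass, with a median log2 fold change of 0.62. IDI1 (1.13, SE 0.15), DHCR7 (1.07, SE 0.11) and EBP (1.03, SE 0.10), enzymes of the pathway, rose, as did its regulator SREBF2 (0.79, SE 0.12). The list had a camera adjusted p of 5.96e-06, and adjusted p = 0.162 with an estimated correlation. Without knockdown array 1, 5 of the 16 rose. The fatty acid metabolism list mixes genes of synthesis and of oxidation, and its counts and test do not separate them. Of its 15 measured genes, 9 rose (10 adjusted over the list alone) and 1 fell, with a median of 0.52. Those that rose included the fatty acid synthase gene FASN (1.49, SE 0.10) and the regulator SREBF1 (1.41, SE 0.13). The desaturase gene SCD (1.16, SE 0.12) and the carboxylase gene ACACA (0.94, SE 0.11) also rose. FASN lies in a run of raised neighbouring genes on chromosome 17, described at the end. CPT1A, which admits fatty acids to mitochondria for oxidation and is named here after its value was seen, fell by 0.50 (SE 0.10), and its call ended when any of the 3 knockdown arrays was left out. For the fatty acid list camera gave an adjusted p of 0.00135, and adjusted p = 0.162 with an estimated correlation.

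Genes induced by low oxygen fell in large part. Of 20 measured members of the hypoxia list, 15 fell, also 15 adjusted over the list alone, and 5 did not pass, with a median log2 fold change of -1.09. The log2 fold change was -2.48 (SE 0.14) for adrenomedullin (ADM), -1.72 (SE 0.11) for NDRG1, -1.60 (SE 0.11) for the hormone gene STC2 and -1.49 (SE 0.12) for VEGFA, the angiogenic growth factor. The list had a camera adjusted p of 3.88e-13, and adjusted p = 0.162 with an estimated correlation. Of 9 glycolysis genes measured, 3 fell (HK2, GAPDH and PGK1) and 1 rose (PGAM1), the same numbers adjusted over the list alone, and the list did not pass (camera adjusted p = 0.145). Without control array 1 or 2 or knockdown array 2, 1 glycolysis gene fell, and without knockdown array 1 or 3, 0 fell by limma, where 4 of the 9 had an unadjusted p under 0.05 in all 6 arrays. After quantile normalization or cyclic loess no glycolysis gene rose, and with median centring 1 fell.

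Part of the growth-factor and inflammatory response genes fell in the knockdown cells. Of 23 measured genes that respond to ERK signalling, 8 fell and 1 rose (12 and 3 adjusted over the list alone), with a median of -0.31. FOS (-2.63, SE 0.15), FOSL2 (-1.46, SE 0.11) and JUN (-1.27, SE 0.13), which encode subunits of the AP-1 factor, fell, as did IER3 (limma adjusted p = 0.00159). CCND1, the cyclin D1 gene, was the member that rose (0.80, SE 0.12), and with median centring 2 members rose. The camera adjusted p was 0.000748, and adjusted p = 0.162 with an estimated correlation. Of 16 NF-kB and cytokine genes, 7 fell, also 7 adjusted over the list alone, with a median of -0.17. They included the adhesion molecule gene ICAM1 (-2.39, SE 0.16), the lipocalin gene LCN2 (2.30-fold lower) and the chemokine genes CCL2 (-0.82, SE 0.14) and CCL20 (-0.72, SE 0.13). This list had a camera adjusted p of 0.00135, and adjusted p = 0.162 with an estimated correlation. The ERK-responsive genes that fell numbered 5 without knockdown array 2 or 3, and the NF-kB genes 4 without control array 2 or any of the 3 knockdown arrays.

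Of 14 measured mesenchymal markers, 4 fell, also 4 adjusted over the list alone, with a median of -0.25. FN1 (-2.64) and the collagen-crosslinking enzyme gene LOX (-1.01, SE 0.16) had the largest changes, followed by the receptor gene AXL (-0.69, SE 0.14) and vimentin (VIM, -0.46, SE 0.12). The camera adjusted p was 0.002, and adjusted p = 0.162 with an estimated correlation. Without knockdown array 1 or 2, 2 of these genes fell, AXL and VIM no longer passing. VIM also lost its call without any 1 of the control arrays or with median centring, and 3 of the genes fell in each of these settings. The basal and stem-like list did not pass (camera adjusted p = 0.106). Of its 11 measured genes, 4 fell (4 adjusted over the list alone), among them SOX9, CD44 (-1.33, SE 0.10) and EGFR (-0.92, SE 0.14), while SOX2, a pluripotency factor, rose by 1.18 (SE 0.11), and 2 genes rose adjusted over the list alone, without control array 2, or after each of 3 other scalings.

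Luminal and hormone-response genes moved both ways. Of 19 luminal identity genes, 4 rose and 3 fell, the same numbers adjusted over the list alone. SPDEF, a luminal transcription factor gene, rose by 1.22 (SE 0.11), the keratin gene KRT18 by 0.69 (SE 0.10) and ESR1, the oestrogen receptor, by 0.66 (SE 0.11, limma adjusted p = 0.00585), while OVOL1 was lower (-0.53, SE 0.11). The list's median (0.01) and mean (0.07) were above 0 and its camera direction was down, with an adjusted p of 0.814. No gene of it fell without control array 3 or knockdown array 2 or 3, and 1 fell without control array 2, without knockdown array 1 or with median centring, against 8 of 19 that changed either way at an unadjusted p under 0.05 in all 6 arrays by limma. Of 21 oestrogen receptor targets, 5 rose and 4 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.303), and the number that fell was 6 after quantile normalization and 7 after cyclic loess. MYBL1 rose by 1.09 (SE 0.13), CCN5 fell by 1.30 (SE 0.13) and the carbonic anhydrase gene CA12 fell by 1.04 (SE 0.10). CA12 and STC2, another target that fell, are also in the hypoxia list. Of 20 cell-cell junction genes, 5 rose, NECTIN1 (1.02, SE 0.11) and CLDN1 (1.02, SE 0.12) among them, and 4 fell, among them NECTIN4 (-1.27, SE 0.10) and the desmosome gene DSP (-1.14, SE 0.11). The counts were 6 and 5 adjusted over the list alone, the median (0.04) and mean (0.05) lay above 0, and the camera direction was down with an adjusted p of 0.953. After quantile normalization or cyclic loess 3 junction genes rose and 5 fell. Without any of the knockdown arrays 3 junction genes rose, and without knockdown array 2 the genes that fell numbered 2. CDH1 (E-cadherin) has no named probe set in the table used here.

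For 4 further lists the camera test passed by a small margin, each with an adjusted p of 0.0487. With an estimated correlation the adjusted p was 0.23 for the p53 and ERBB lists and 0.195 for the Notch and 15q25 lists. Of 14 p53 targets, 4 fell (4 adjusted over the list alone), with GDF15 at -1.67 (SE 0.13) and EDA2R at -1.27 (SE 0.12). Of 22 Notch pathway genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone), with the co-activator gene MAML2 at -1.64 (SE 0.14), the ligand gene JAG1 at -1.09 (SE 0.10) and HEY2 at 0.98 (SE 0.11). The ERBB list was drawn up from receptors, their ligands, and ERRFI1 and GRB7, which are neither. Of its 14 measured genes, 2 fell and 1 rose (2 and 1 adjusted over the list alone). ERRFI1, a feedback inhibitor of EGFR, fell by 1.89 (SE 0.11), EGFR fell by 0.92 (SE 0.14) and ERBB4 rose by 1.09 (SE 0.10), while ERBB3 stood at -0.30 (SE 0.10) and did not pass (limma adjusted p = 0.0873), though it was called lower in 5 other settings, quantile normalization among them (limma adjusted p = 0.0419). The ERBB genes that fell numbered 3 after quantile normalization or cyclic loess. The 15q25 list holds genes near LINC00052, and the band is only its title, since the bands of its members were not checked. Of its 14 measured genes, 6 fell and 1 rose (6 and 3 adjusted over the list alone), against 4 and 3 with median centring. ABHD2, a lipase gene, stood at -1.34 (SE 0.10), MFGE8 at -1.32 (SE 0.11) and MRPS11, of the mitochondrial ribosome, at 0.76 (SE 0.11). HAPLN3 was lower (limma adjusted p = 0.00603). The p53 and 15q25 lists share 1 measured gene. Leaving out a single array ended the p53 call for each array but knockdown array 1 (adjusted p up to 0.0751), the ERBB and 15q25 calls for each but knockdown array 2 (up to 0.0676 and 0.0699), and the Notch call for control arrays 1 and 3 and knockdown arrays 1 and 3 (up to 0.0687). Without control array 3, 1 p53 target rose. The genes that fell numbered 2 in the p53 list without knockdown array 2 or 3, 2 in the Notch list without any of the knockdown arrays, and 3 in the 15q25 list without control array 1 or knockdown array 2 or 3.

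**Figure D2:**
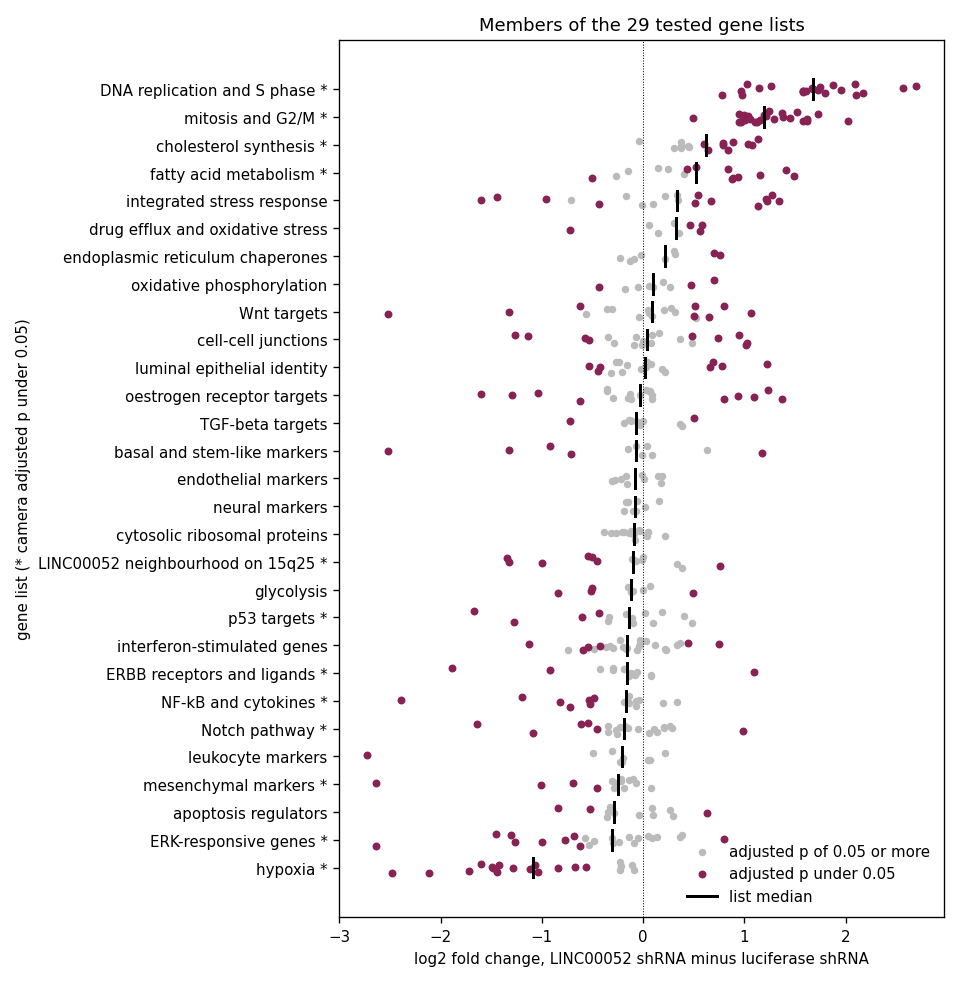
Log2 fold change of each measured member of the 29 tested lists (points, coloured where limma's adjusted p was under 0.05) with the list median as a black bar and an asterisk where camera passed. The replication (median 1.67) and mitosis lists lie wholly above 0 and the hypoxia list (-1.09) lies lowest.

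Stress and biosynthesis lists outside those did not pass camera. Of 19 integrated stress response genes, 8 rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.244). The tRNA synthetase genes AARS1 (1.34, SE 0.12) and GARS1 (1.22, SE 0.12) rose, whereas STC2 (-1.60, SE 0.11) and DDIT4 (-1.45, SE 0.16) fell. STC2 and DDIT4 are also in the hypoxia list. Without knockdown array 2 or 3, 5 of these genes rose, and without control array 2 or knockdown array 2, 2 fell. Of 9 endoplasmic reticulum chaperones, 2 rose, SDF2L1 and HYOU1, and of 8 genes of drug efflux and oxidative stress, 3 rose, TXN (0.58, SE 0.10), TALDO1 (0.56, SE 0.11) and GSR (0.46, SE 0.10), and HMOX1 fell (-0.72, SE 0.16). Adjusted over the list alone or with median centring, 3 chaperones rose, and adjusted over the list alone 5 genes of the efflux list rose and 1 fell. The camera adjusted p was 0.267 for the chaperones and 0.106 for the efflux list, where 1 gene rose without knockdown array 1 or 3 and HMOX1 lost its call without control array 2 or 3 or knockdown array 1 or 2. Of 9 oxidative phosphorylation genes, COX7B (0.70, SE 0.14) and UQCRC1 (0.47, SE 0.11) rose and COX6C (-0.43, SE 0.10) fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.576), and each of these 3 calls ended without at least 2 of the arrays. After quantile normalization or cyclic loess 1 of these genes rose, and with median centring none fell. None of 17 cytosolic ribosomal protein genes passed limma, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Their list was not called (camera adjusted p = 0.106), but it was called lower after quantile normalization (adjusted p = 0.0075), and 2 of its genes fell after cyclic loess. Of 7 genes of the small RNA machinery, too few to test, DGCR8 (0.88, SE 0.11), TNRC6C (0.91, SE 0.14) and XPO5 (0.72, SE 0.13) rose, against 5 adjusted over the list alone.

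Among signalling and immune lists, 5 of 19 Wnt targets rose, led by the inhibitor gene DKK1 (1.07, SE 0.12), and 3 fell, including SOX9 and CD44 (5 and 5 adjusted over the list alone). The Wnt median (0.09) was above 0, the mean (-0.04) below it and the camera direction up (adjusted p = 0.953), and 2 genes rose without knockdown array 1 or 2. Of 11 TGF-beta targets, BAMBI rose and BMP4 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.584), and no gene of the list rose without knockdown array 1 or 2. Of 13 apoptosis regulators, the anti-apoptotic gene BCL2L1 rose (0.63, SE 0.12) and the pro-apoptotic genes PMAIP1 (-0.84, SE 0.11) and BMF (-0.53, SE 0.14) fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.145). BCL2L1 lost its call without knockdown array 1, and BMF without each array but control array 1. The regulators that fell numbered 5 after quantile normalization or cyclic loess and 1 with median centring. Of 25 interferon-stimulated genes, HERC6 (0.75, SE 0.11) and 1 other rose and 4 fell, among them BST2 (-1.13, SE 0.18) and IRF9 (-0.60, SE 0.13). The counts were 3 and 6 adjusted over the list alone (camera adjusted p = 0.137), 1 rose whichever array was left out, and the number that fell was 1 without any of the knockdown arrays and 2 without control array 1 or with median centring. Both measured antigen presentation genes, B2M and TAPBP, fell, over all genes and adjusted over the list alone, and 1 of them fell without any of the knockdown arrays. The genes of the chaperone, TGF-beta and antigen presentation lists were named after their values were seen.

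Few markers of other cell types passed limma. The leukocyte list had a median log2 fold change of -0.21 and a mean of -0.43, and fry called it lower (adjusted p = 0.0173). CD68, which macrophages and many cancer lines express, was the 1 called gene among 9 leukocyte markers (also 1 adjusted over the list alone, and 2 without knockdown array 3; camera adjusted p = 0.143). It fell from 9.38 ± 0.22 to 6.65 ± 0.04 (SD, n = 3 each). No gene passed limma among 10 endothelial markers (camera adjusted p = 0.502), 8 neural markers (0.347), 7 fibroblast markers or 4 integrin and matrix genes, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there was 1 endothelial marker, and 0 in each of the other 3 lists, and 1 endothelial marker fell after quantile normalization.

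Of 34 lists, 29 had at least 8 measured genes, and 12 of these passed camera, 4 higher and 8 lower. With an estimated correlation 0 of the 29 passed and 8 had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance one way, without comparing them with other genes, 22 passed. Of the 108 named genes that passed limma, 20 lost the call with at least 1 of the 6 arrays left out: AXL, BCL2L1, BMF, COX6C, COX7B, GAPDH, GSR, HK2, HMOX1, IFITM1, IRF9, NOTCH2, OVOL1, PGAM1, PGK1, SESN1, SPATA18, TALDO1, UQCRC1 and VIM. Each change above is relative to the arrays' common level as deposited.

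**Figure D3:**
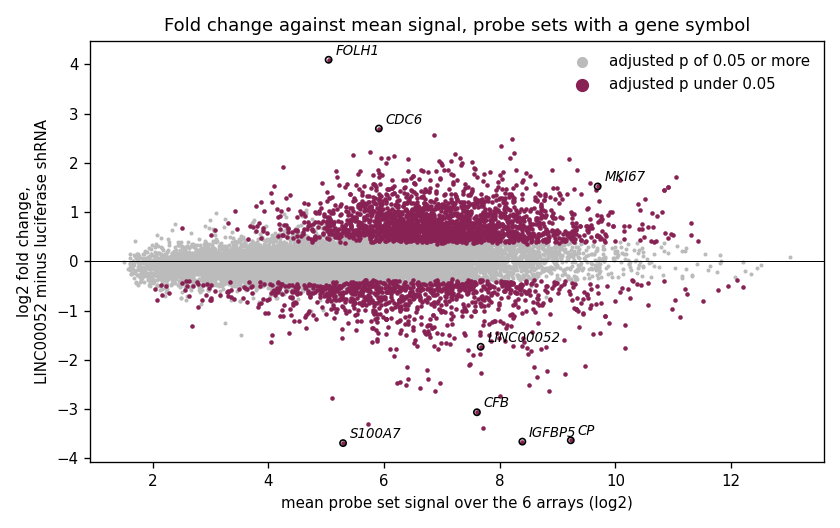
Log2 fold change against the mean signal over the 6 arrays (log2) for the 16098 probe sets with a gene symbol, coloured where limma's adjusted p was under 0.05. Over all 48226 probe sets, split into 4 equal groups by mean signal, 20.8% of the calls in the dimmest group were higher in the knockdown cells and 66.9% of those in the brightest group.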

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

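LINC00052 stayed lower under each alternative, with a log2 fold change between -1.875 and -1.673 and an adjusted p of at most 0.00575 in the settings other than left-out arrays. The count of changed probe sets (6562) was 4200 when only probe sets with a symbol were tested, with 712 in place of 1379 at 2-fold, both because fewer were tested, and 2559 against a fold of 1.2, a stricter question. With 1 array left out it ranged from 3574 to 5752, with fewer samples. All other settings but the replicate block gave 6157 to 8270, and the share higher ranged from 52.6% (cyclic loess) to 68.7% (median centring). Same-numbered samples did not deviate together (r = -0.0492, -0.0464 and -0.148). No effect shared by them was thus seen, which does not show whether they were prepared together. With the replicate block 4161 probe sets and 8 lists were called, and 16 of 107 named calls besides LINC00052 ended. Of 12 lists called, 0 passed with an estimated correlation, where the cause was not tested, and fry, which asks another question, called 22. With an array left out 8 to 11 lists were called. In other settings the p53, Notch, ERBB and 15q25 lists were those that lost calls: ERBB and 15q25 after quantile normalization (adjusted p = 0.0773 and 0.0551) and cyclic loess (0.0844 and 0.0531), ERBB without the dimmest probe sets (0.0579), the 4 by ranks, and p53, Notch and 15q25 with the mean of a gene's probe sets. The cytosolic ribosomal list was called lower after quantile normalization (0.0075) and cyclic loess (0.00416). Of 108 called named genes, 20 lost the call without at least 1 array, and 24 missed it against a fold of 1.2: these 20 and ESR1 (adjusted p = 0.0539), CCL20 (0.0612), XPO5 (0.0653) and TXN (0.0927). ERBB3, not called as deposited, was called lower in 5 settings (adjusted p from 0.0038 to 0.0419). No called direction reversed. Signal over background was not given, and 2.39% of the dimmest probe sets were called against 36.1% of the brightest.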

Other observations

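The gene families and all tests here but the splits of the arrays were chosen after the results they bear on were seen, the test without the GOLGA genes included, though its predicted outcome was written before it was run. Many genes for making protein in mitochondria rose: of 73 measured protein-coding genes with the MRPL or MRPS prefix, which encode proteins of the mitochondrial ribosome, 46 rose, with a median log2 fold change of 0.58 and MRPL58 (1.47, SE 0.15), MRPS7 (1.29, SE 0.15) and MRPL38 (1.27, SE 0.11) leading. MRPL58 and MRPS7 lie in a run of raised neighbouring genes on chromosome 17, described below. Of 13 TIMM genes, which import proteins into mitochondria, 9 rose. Of 17 aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 12 rose, among them MARS1 (2.04, SE 0.18), AARS1 (1.34, SE 0.12) and GARS1 (1.22, SE 0.12). All 17 are of the mainly cytosolic type, and none of the separate mitochondrial synthetase genes was among them. Of 22 protein-coding genes with the NUP prefix, mostly of the nuclear pore, 13 rose, NUP188 (1.21, SE 0.13) and NUP205 (1.17, SE 0.11) among them, and of 10 exosome genes (EXOSC), which degrade RNA, 8 rose. By limma's camera over 208 families of protein-coding genes the adjusted p was 5.33e-15 for the mitochondrial ribosome, 4.35e-06 for the synthetases, 1.54e-07 for NUP, 1.27e-05 for TIMM and 0.000881 for EXOSC. With an estimated correlation it was 0.46, 0.536, 0.536, 0.46 and 0.536 in the same order. After each of 3 other scalings of the arrays the medians of these 5 families stayed above 0, between 0.46 and 0.65 for the mitochondrial ribosome.

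Of 16 S100A genes, 5 fell, including S100A7 (-3.69, SE 0.26), S100A8 (-1.93, SE 0.16) and S100A9 (-1.07, SE 0.19), and 2 rose. When any array other than control array 3 was left out, 4 fell and 1 rose. The family had a camera adjusted p of 0.0333 in limma, and adjusted p = 0.536 with an estimated correlation. Of 11 CEACAM genes, 3 fell, with CEACAM5 at -3.38 (SE 0.12) and CEACAM6 at -2.50 (SE 0.17), and the family did not pass (adjusted p = 0.068).

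Too few splits of the 6 arrays into 3 and 3 exist (10) for a share under 0.05. The real split, the 1 with the most, called 6562 probe sets and 1379 at 2-fold with limma. The highest of the other splits called 0 of either, with at most 2332 probe sets at an unadjusted p under 0.05. Each other split mixes arrays of both groups, so a difference between the groups widens the spread on each side. Low counts there were thus likely in advance, whatever caused the difference, and decide nothing about its cause. For the gene lists the real split, again the 1 with the most, called 12, and the highest of the others called 6.

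The rise of the 47 cell cycle genes (median 1.38) and the fall of most hypoxia genes went together. A shift between arrays that follows the signal level is argued against, since after cyclic loess the medians were 1.26 (SE 0.13, 47 of 47 higher) and -1.2 (SE 0.24, 20 of 20 lower). So is control array 2 alone for the cell cycle rise, since without it that median was 1.29 (SE 0.12). The SEs in this paragraph come from resampling the genes of a list, taken as independent, and do not measure the spread between arrays. A growth state of the dishes, such as their density, cannot be told apart from an effect of the LINC00052 hairpin on growth, since each group had its own dishes: control array 2 differed from the other control arrays by -0.493 in cell cycle minus hypoxia level, but it was picked because it lay farthest, so this decides nothing. The cell cycle minus hypoxia level was -1.44, -2 and -1.58 in the control arrays and 0.76, 0.8 and 0.912 in the knockdown arrays. Both explanations stay open, and so does a difference between the stable lines.

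Neighbouring genes shifted together in 4 runs of 25 genes, in the gene order of the GRCh38.p14 table and after removal of the trend with signal: ARHGDIA to TBCD (0.68) and TEX2 to MIF4GD (0.53) were higher on chromosome 17, and COPS2 to ANXA2 (-0.54) and GOLGA6L10 to PEX11A (-0.55), which holds LINC00052, were lower on chromosome 15. Chance order is argued against, since at most 13 of 1000 shuffled orders held a run as extreme as any of these. GOLGA genes are paralogs that could share probes. Without them the run that holds LINC00052 did not stand out against the most extreme run of each shuffled order. Its 21 other genes had a median of -0.373. The most extreme run of 25 genes holding LINC00052, which takes in further neighbours, had -0.353, which 923 of 1000 shuffled orders reached. The run was picked for its extreme median, and leaving out other members was not tried. A weaker median was thus likely in advance, and shared probes are neither shown nor excluded. For all 4 runs a difference in gene copy number between the stable lines and shared regulation of neighbours cannot be told apart without DNA data. Both predict that most genes of a run move its way, and at least 76% did. The runs were picked by their medians, which favours a high share, so the share decides nothing. A copy-number difference between the lines might thus account for part of the calls on chromosomes 15 and 17. FASN lies in the ARHGDIA to TBCD run. MRPL58, MRPS7 and NUP85 lie in the TEX2 to MIF4GD run, as does SOX9, which fell.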
